A study of Homo sapiens with 4 samples.

How the data were processed

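The series measured where Argonaute 2 (AGO2), the protein that carries microRNAs to their target RNAs, contacts RNA in 2 human B cell lines. DG75 is a Burkitt lymphoma line that does not carry Kaposi's sarcoma-associated herpesvirus (KSHV); the labels name the cells used DG75-eGFP. BCBL-1 is a primary effusion lymphoma line that carries KSHV and so expresses viral microRNAs. There were 4 libraries, replicates A and B of each line. In PAR-CLIP, cells take up 4-thiouridine, ultraviolet light crosslinks the labelled RNA to bound protein, the protein is precipitated, and the attached RNA is sequenced. Per the labels' protocols, cells received 100 µM 4-thiouridine for 14 h and 2 pulses of 100 mJ at 365 nm, and the precipitating antibody was 11A9, which is directed at AGO2.

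Reads were processed by the submitters. The submitters' processing notes name Bowtie 0.12.7 and the genome build hg19; the caller of the clusters, its filters, the treatment of reads with several genomic matches and the pooling of replicates are not given in the sources used here. The list analysed here was 1 file for the whole series, with a chromosome, start, end, strand and name for each cluster. The deposited score was 1000 for every cluster, so it carried no ranking and was not used. No column named a library or a cell line. Read counts behind the clusters were not used here, so the depth per library is unknown and no interval for a library could be given.

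The designs fixed before the data were examined included tests between DG75 and BCBL-1, the overlap of the lists of the lines and the viral seed matches of one line against the other. These comparisons were not analysed here, because the list does not tell the lines apart. What follows therefore describes the clusters of both lines together. P-values compare clusters with background windows, or listed genes with other genes; they do not measure the spread between replicate libraries. Overlapping clusters are not independent of each other, so p-values over clusters are too small to that extent.

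Cluster positions were compared with the GRCh37 primary assembly and with GENCODE release 44 lifted to GRCh37, and are given 1-based in hg19 coordinates. For the mitochondrial chromosome the reference sequence differed from the one the positions refer to: G preceded 8.37% of its 239 clusters (95% exact interval 5.19% to 12.6%) against 87.5% of nuclear clusters. With the reference read 1 nt lower, G preceded 60.7% of the mitochondrial clusters. Coordinates were not converted, and the mitochondrial clusters were left out of annotation, sequence and gene analyses. That left 27394 nuclear clusters.

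Each nuclear cluster was assigned to a region at its midpoint on its own strand, with the priority 3' UTR, coding exon, 5' UTR, intron, non-coding exon, intergenic. Introns preceded non-coding exons in this order, so a non-coding transcript inside an intron of another gene was counted as intron. Shares carry 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only. For the seed analysis, the 42 listed human and KSHV microRNA sequences gave 41 different 7mers, each the reverse complement of bases 2 to 8 of a microRNA. MiR-155 and miR-K12-11 share their 7mer. The list held 5 families of microRNAs typical of liver, muscle or brain as controls. The share of clusters with the 7mer was divided by the share of windows of equal width lying 200 nt upstream and 200 nt downstream. Fisher's exact test was two-sided, with Benjamini-Hochberg adjustment over the 41 families and a threshold of 0.05. Ratio intervals are 95% intervals on the log scale. The flanks of a cluster in a coding exon often lie in introns, so their base composition differs from that of the cluster.

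The 13 gene lists and the microRNA seeds were written before the data were examined. A gene was counted when at least 1 cluster midpoint lay in an exon of a protein-coding transcript of it. Protein-coding genes of chromosome Y and of the mitochondrial chromosome were left out, which left 20098 genes. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, adjusted over the 13 lists. In a test added after seeing the data, the number of list genes with a cluster was compared with random draws at the rate of genes in the same of 20 bins of 3' UTR length. These tests are not adjusted for expression, because AGO2 clusters are found only in genes that are expressed and no expression values were used. NHP2L1 was matched under its current symbol SNU13, and PRG1 had no match. Genes named in the text are the 5 genes with most clusters and, in each list, up to 4 genes with most clusters; 1 gene that this rule names is not reported here. The fixed rule also named the 15 clusters with the highest score; with all scores equal it gave no ranking and was not applied. For some lists, all genes without a cluster are named as well. Other genes are said to have been chosen after their values were seen.

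The seed test was tested on simulated data: in 13697 mock clusters drawn from flanking windows, 5 of 5 families with implanted matches were recovered and 0 of 36 others were called. The smallest implanted enrichment was 1.5-fold. Mock clusters and their background both came from flanking windows. The 0 of 36 therefore does not measure false calls in real clusters, whose base composition differs from that of windows. The list test, on 20098 genes with simulated clusters, recovered 3 of 3 enriched lists of 20 genes and called 0 of 10 others. Enriched lists were built with 18 genes with a cluster, and the others at the overall rate. With these counts fixed, the outcome measures no error rate, and weaker enrichment of lists was not simulated. Alternatives fixed before the data were examined were merging of overlapping clusters for the cluster count, annotation by any overlap, annotation without strand, 6mers, clusters widened by 10 nt, dinucleotide-shuffled copies (10 per cluster) or the antisense strand as background, and genes with any cluster as background for the lists. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pyfaidx 0.9.0.4 and matplotlib 3.10.9, and with samtools 1.23.1.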

Results

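AGO2 PAR-CLIP of DG75 and BCBL-1 B cells, with 2 replicate libraries per line, was carried out to map microRNA target sites. The combined list held 27633 clusters, which are stretches of RNA with crosslinked reads. They lay on both strands in similar numbers, 14008 on the plus and 13625 on the minus strand. The median cluster was 54 nt wide (quartiles 42 and 65 nt, range 18 to 125 nt). In 1955 clusters the reads spanned a splice junction, and 1951 of these junctions (99.8%) were annotated introns. Of the clusters, 27394 were nuclear and 239 mitochondrial. Every nuclear cluster contained at least 1 T, the base whose thio analogue is crosslinked: 0 of 27394 lacked one, which allows a share of up to 0.0110%. The median was 16 T per cluster and no background share was measured, so this count does not test crosslinking. The list carries neither a library nor a cell line for a cluster, so all values below belong to both lines together and have no replicate error.

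AGO2 clusters were found mainly in mature mRNA, most often in 3' UTRs. Of the nuclear clusters, 15058 (55.0%, 95% interval 54.4% to 55.6%) lay in a 3' UTR and 7288 (26.6%) in a coding exon. Introns held 2803 clusters (10.2%), intergenic sequence 1480 (5.40%), exons of non-coding transcripts 397 (1.45%) and 5' UTRs 368 (1.34%). In genes with a cluster, 3' UTRs carried 0.973 clusters per kb (bootstrap 95% interval over 6211 genes 0.937 to 1.01) and coding sequence 0.645 per kb. The ratio of the densities was 1.51 (1.43 to 1.58). When non-coding exons were placed before introns, an order chosen after seeing the data, introns held 1855 clusters (6.77%) and non-coding exons 1345 (4.91%), among them 532 on microRNA hairpins and 430 in long non-coding RNAs. With strand ignored, the intergenic share was 3.37%.

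**Figure D1:**
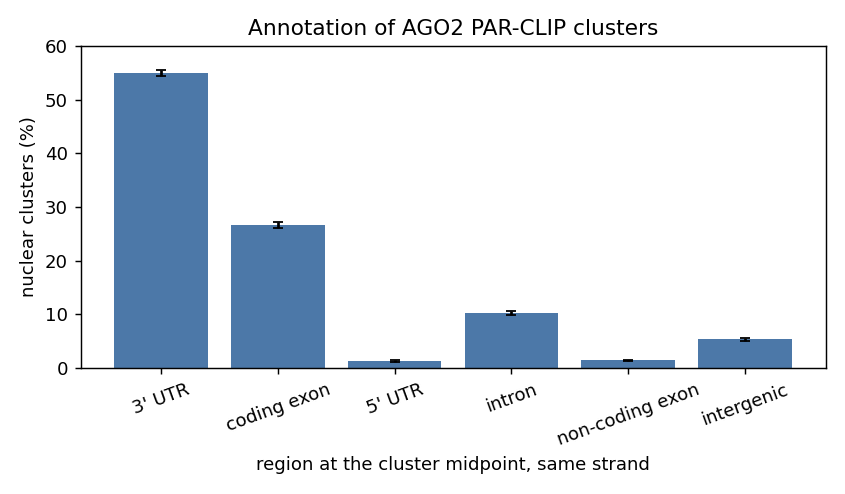
Percent of the 27394 nuclear clusters (y axis) in each region at the cluster midpoint (x axis); bars are shares and error bars 95% exact binomial intervals. The 3' UTR bar stands at 55.0% and the coding exon bar at 26.6%.

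Within long 3' UTRs the clusters were concentrated toward both ends. In the 2462 genes with clusters in a 3' UTR of at least 2000 nt, the first of 10 equal bins, next to the stop codon, held 18.5% of the 9330 clusters (bootstrap 95% interval over genes 17.4% to 19.5%). The share fell to 6.93% (6.31% to 7.57%) in bin 7 and was 11.2% in bin 10.

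**Figure D2:**
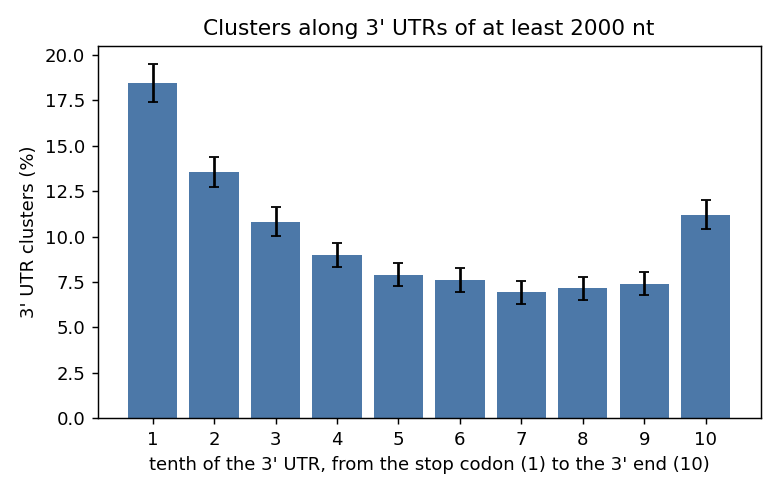
Percent of 9330 clusters (y axis) in each of 10 equal bins of 3' UTRs of at least 2000 nt, from the stop codon to the 3' end (x axis), in 2462 genes; error bars are 95% bootstrap intervals over genes. Bin 1 holds 18.5%, bin 7 6.93% and bin 10 11.2%.

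Most of the listed human and KSHV seeds were over-represented in the clusters, some of them strongly. The highest ratio belonged to miR-142-3p, a microRNA of blood cells, whose 7mer ACACTAC occurred in 860 clusters (3.14%) and 12.9 times more often than in flanking windows (95% interval 10.8 to 15.5). The next highest was miR-19a/b, a member of the miR-17-92 cluster known as an oncogene in B cell lymphomas, at 6.87 (914 clusters, 3.34% against 0.486% of windows). The miR-17 family (miR-17, miR-20a, miR-93 and miR-106b), part of which is encoded in the same cluster, was enriched 5.64-fold (5.04 to 6.32, 1117 clusters). Further human families with high ratios were miR-130/miR-301 at 6.40, miR-15/16 at 4.86, miR-25/92a at 3.96 and miR-103/miR-107 at 3.78. Some human sites share 6 bases, such as TTTGCAC of miR-19a/b and TTGCACT of miR-130/miR-301. The sites TGCTGCT of miR-15/16 and ATGCTGC of miR-103/miR-107 do so too. A cluster can then count for both families, so their ratios are not separate evidence for each microRNA. In all, 32 of the 41 families were enriched (Fisher's exact test, adjusted p under 0.05), 2 were depleted and 7 were not called. The size of the ratios depended on the background: for miR-142-3p it was 5.83 against dinucleotide-shuffled copies of the clusters, for miR-19a/b 4.44 against shuffled copies and 11.9 against the antisense strand, and for the miR-17 family 15.1 against the antisense strand.

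Among the KSHV families, 9 of 11 were enriched, with a median ratio over the 11 of 2.83. MiR-K12-10a led with 6.34 (5.25 to 7.66, 447 clusters), ahead of miR-K12-4-3p at 4.84 (4.11 to 5.70, 486 clusters), miR-K12-6-3p at 4.66 (254 clusters) and miR-K12-7 at 4.24 (331 clusters). MiR-K12-8, at 1.10 (0.689 to 1.76), and miR-K12-12, at 0.848 (0.703 to 1.02), were not called; miR-K12-12 stood at 1.55 against shuffled copies and miR-K12-8 at 3.00 against the antisense strand, both past the threshold. Against shuffled copies miR-K12-10a was enriched 2.20-fold, miR-K12-6-3p 2.42-fold and miR-K12-3 6.25-fold. The 7mer shared by human miR-155 and viral miR-K12-11 was present in 253 clusters and enriched 2.42-fold (2.02 to 2.91); matches to the human and the viral microRNA cannot be separated by this 7mer. Some viral sites overlap human ones, for example those of miR-K12-10a and miR-142-3p. After all clusters and windows with a 6mer of the 5 most enriched human families were left out, a test chosen after seeing the data, miR-K12-10a was still enriched 5.59-fold (4.20 to 7.44), miR-K12-4-3p 6.07-fold and miR-K12-7 5.55-fold. Only 141 of the 447 miR-K12-10a clusters remained, against 405 of 486 for miR-K12-4-3p and 276 of 331 for miR-K12-7. Most miR-K12-10a clusters therefore also held a 6mer of these human families. The control miR-122 also stayed enriched there, at 2.37 (1.77 to 3.18), as did miR-1/miR-206 at 1.69. Among all clusters TAACACT, which is the site of no listed family and ends in the same 6 bases as the miR-K12-10a site CAACACT, had a ratio of 6.85, so matches to miR-K12-10a were not separated from sites of like sequence. The site of miR-K12-6-5p holds such a 6mer and could not be tested in this way.

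Of the 24 other human families, 20 were enriched, among them miR-181 (3.00), let-7 (2.52), miR-30 (2.14) and miR-21 (1.80). MiR-150, a microRNA of mature lymphocytes, was depleted at 0.463 (0.375 to 0.570, Fisher's exact test, adjusted p = 1.49e-14), and miR-24, miR-221/miR-222 and miR-146 were not called. Against shuffled copies the miR-150 ratio was 1.13, and among 3' UTR clusters with both flanks in a 3' UTR, chosen after seeing the data, it was 0.767 and no longer past the threshold. MiR-24 stood at 1.65 against shuffled copies and at 0.768 with 6mers, both past the threshold. Of the 5 control families of other tissues, 2 were enriched, the liver microRNA miR-122 at 2.14 and the muscle family miR-1/miR-206 at 1.78, and miR-124, of the brain, was depleted at 0.767; their median was 1.21. These 2 ratios lay in the range of called human and viral families such as miR-34a (1.97), miR-K12-1 (2.10) and miR-K12-5 (1.71). MiR-124 stood at 1.16 against the antisense strand. Among reordered 7mers of the same letters, a background chosen after seeing the data, 74.7% lay below miR-K12-5 and 89.7% below miR-K12-1. Neither control enrichment held against every background, since miR-122 stood at 0.912 against shuffled copies and miR-1/miR-206 at 0.890 against the antisense strand.

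**Figure D3:**
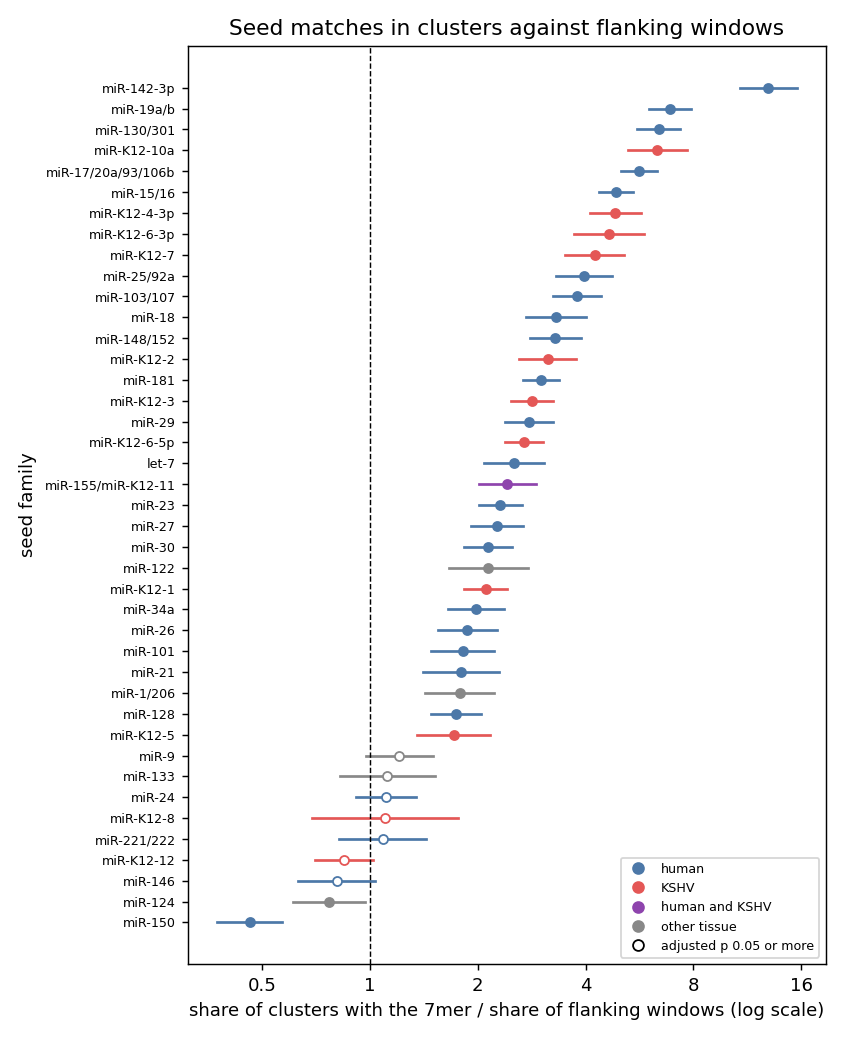
Ratio of the share of clusters with a family's 7mer to the share of flanking windows (x axis, log scale) for 41 seed families (y axis), coloured by origin; lines are 95% intervals and open circles families not past the threshold. MiR-142-3p is highest at 12.9 and miR-150 lowest at 0.463.

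A match to any of the 30 human or viral families found enriched in these clusters, a choice that by itself places the ratio above 1, was present in 36.6% of nuclear clusters (36.0% to 37.2%) and 11.6% of flanking windows, a ratio of 3.15 (3.06 to 3.24). Clusters in 3' UTRs had a match in 40.0% (39.2% to 40.8%), those in coding exons in 36.0% (34.9% to 37.1%) and those in introns in 30.9% (29.2% to 32.6%). Intergenic clusters had one in 21.9%. Intron and intergenic clusters were narrower (median widths 34 and 28 nt against 56 nt in 3' UTRs), which leaves room for fewer chance matches. Over flanking windows of equal width the ratio was higher in introns, at 4.21 (3.78 to 4.69), than in 3' UTRs, at 3.09 (2.98 to 3.20), and was 3.48 (2.94 to 4.13) in intergenic sequence. Clusters on microRNA hairpins, which may represent the microRNA itself rather than a target, had one in 8.63% (6.45% to 11.2%). Their ratio over flanking windows was 1.48 (1.04 to 2.12).

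In 23 of the 32 enriched families, matches lay nearer the middle of the cluster than of flanking windows, with 95% intervals apart; in the other 9, among them miR-155/miR-K12-11 (65.6% and 64.1%) and miR-30 (61.7% and 57.5%), the intervals overlapped. This held for none of the 9 families not enriched, and miR-9 matches lay farther from the middle (37.8% and 57.7%). Of the matches to miR-19a/b, 81.3% (78.6% to 83.8%) had their centre in the central 50% of the cluster, against 60.2% (54.0% to 66.1%) in flanking windows. For miR-142-3p these shares were 73.8% and 59.7%, and for miR-K12-10a 77.2% and 51.6%. An A directly after the match, opposite the first base of the microRNA, followed 43.5% of miR-17 family matches in clusters (40.6% to 46.5%) and 15.3% in flanking windows. The shares were 51.5% and 25.8% for miR-K12-10a, whereas for miR-19a/b they were 39.3% and 40.2%. For miR-142-3p they were 51.2% and 46.8%, with overlapping intervals. An A after the miR-K12-10a site CAACACT also forms most of the miR-142-3p site ACACTAC. The excess of A at miR-K12-10a matches therefore cannot be assigned to the viral microRNA.

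**Figure D4:**
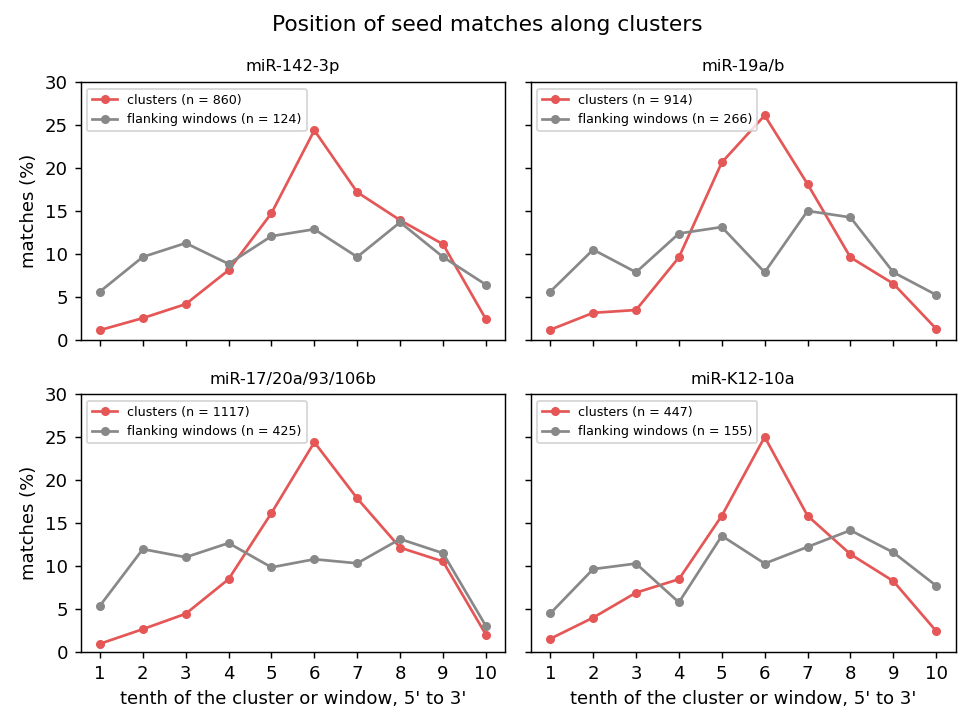
Percent of 7mer matches (y axis) in each of 10 equal bins of the cluster or flanking window from 5' to 3' (x axis) for 4 families; red is clusters, grey flanking windows. Matches in clusters peak in bin 6, while those in windows are spread along the window.

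Clusters were found in exons of 6250 of 20098 protein-coding genes (31.1%). The median such gene had 2 clusters, and 451 genes had 10 or more. IRF4, a transcription factor of activated B cells and plasma cells on which primary effusion lymphoma lines depend, had the most with 58, of which 48 lay in its 3' UTR (chromosome 6, 407599 to 411443, plus strand). Of these 48, 10 held a match to an enriched family, including 4 for miR-34a, which form 2 overlapping pairs, and 3 for miR-30, which overlap each other. Among all 3' UTR clusters 40.0% held such a match, a larger share than in IRF4. Counts of clusters per gene were not adjusted for expression. TNRC6A, the AGO partner GW182, had 56 clusters (25 in the 3' UTR), and 4 of its clusters, all in coding exons and 2 of them overlapping, held a miR-142-3p match. SETD5, a chromatin regulator, had 48 clusters, CCND2, the cell cycle driver cyclin D2, 46, and NUFIP2, an RNA-binding protein, 44.

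**Figure D5:**
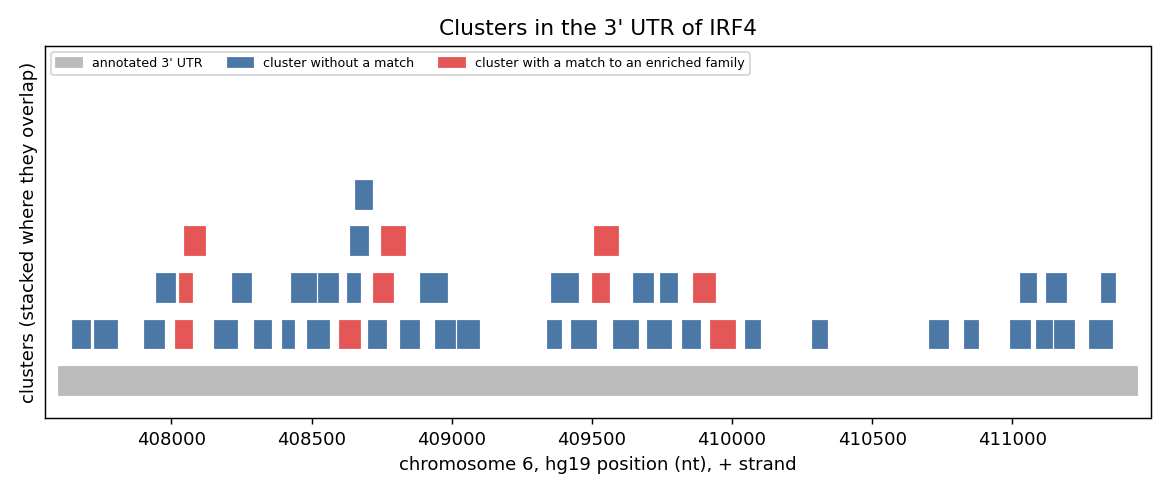
Clusters over the 3' UTR of IRF4 by hg19 position on chromosome 6 (x axis), stacked where they overlap (y axis, no unit). Red marks the 10 clusters with a match to an enriched seed family, blue the other clusters and grey the annotated 3' UTR from 407599 to 411443.

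Genes reported as targets of KSHV microRNAs, miR-155, the miR-17-92 cluster and let-7 often carried clusters. A gene counted with any cluster, whatever seed match the cluster held. Of the 19 measured reported KSHV microRNA targets, 13 (68.4%) had a cluster against 31.1% of other genes (Fisher's exact test, adjusted p = 0.00195). The angiogenesis inhibitor THBS1 had 43 clusters; 3 overlapping ones on chromosome 15 between 39889500 and 39889617, in its 3' UTR, held a miR-K12-3 match. The cell cycle inhibitor CDKN1A had 13 clusters, 1 with a miR-K12-1 match at 36654891 to 36654956 on chromosome 6, and the transcription factor NFIB had 21. Of the reported miR-155 targets, 12 of 20 had a cluster (adjusted exact p = 0.0110). The transcriptional repressor BACH1 had 10, of which 2, at 30717290 to 30717354 and 30717352 to 30717426 on chromosome 21 in the 3' UTR, held the 7mer shared by miR-155 and miR-K12-11. ZNF652 had 16 clusters, of which 3 held this 7mer, 2 of them overlapping. WEE1, a kinase that delays mitosis, had 16 and TP53INP1 17, each with 1 such cluster. Overlapping clusters can hold the same site.

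Of the reported miR-17-92 targets, 16 of 20 had a cluster (adjusted exact p = 2.99e-05). They included the death promoter BCL2L11 with 15 clusters, all in its 3' UTR, and the transcription factor E2F3 with 13. Of the reported let-7 targets, 16 of 20 had a cluster (adjusted exact p = 2.99e-05), among them LIN28B, which blocks let-7 maturation, with 13 clusters, 2 of them with a let-7 match, and HMGA1 with 12. HMGA1 had no cluster with a let-7 match, and neither had CCND2, which is also on this list. The microRNA machinery itself was the list with the highest share: 19 of 20 genes had a cluster (adjusted exact p = 4.14e-08), with 35 clusters in TNRC6B, 29 in AGO2 and 15 in DDX6. GEMIN4 had none. Among the AGO2 clusters, 3 held a miR-103/miR-107 match, 2 of them overlapping.

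Regulators of proliferation and survival also carried clusters often. Of the cell cycle regulators, 18 of 20 had one (adjusted exact p = 4.48e-07), CCND1 and RBL2 being the exceptions, and CDKN1B, the inhibitor p27, had 14. Of the apoptosis regulators, 15 of 20 had one (adjusted exact p = 0.000177), with 26 in the survival factor MCL1 and 12 in CASP8; BCL2, BCL2L1, BBC3, CASP9 and FAS had none. Of the NF-kB signalling genes, 12 of 20 had one (adjusted exact p = 0.0110), with 13 in TAB2, 6 in MAP3K7, 4 in REL and 3 in NFKBIA.

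Plasma cell markers carried clusters more often than other genes and B cell markers did not. Of the plasma cell markers, 9 of 12 had a cluster (adjusted exact p = 0.00416): besides IRF4, the regulator of plasma cell development PRDM1 had 12, SLAMF7 11 and SDC1, the surface marker CD138, 7. Of the B cell markers, 5 of 16 had one (31.3%, adjusted exact p = 1.0), with at most 3 clusters in a gene: FCRLA had 3, and CD79A, CIITA and MS4A1 2 each. The difference between both marker lists did not pass the threshold (Fisher's exact test, p = 0.0542). Among markers of other cell types, 1 of 12 T cell genes (LCK), 1 of 12 myeloid genes (CEBPB) and 1 of 10 epithelial genes (KRT18) had a cluster, and none of these lists was called, with adjusted exact p of 0.142, 0.142 and 0.205. When lists were compared with random draws from genes of like 3' UTR length, a test added after seeing the data, 7 of the 9 calls held, and those of the miR-155 targets and NF-kB genes did not. Against genes with a cluster anywhere, introns included, 0 of the 13 lists were called by Fisher's exact test, and 0 had an unadjusted p under 0.05.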

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

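The mitochondrial clusters lie outside the data analysed in the report and exceed the 3 that a count of 0 allows. There were 239, of which 193 lay on the plus strand and covered 9936 nt, and 46 lay on the minus strand and covered 2457 nt. One candidate explanation is abundant mitochondrial RNA recovered without microRNA pairing, which would give no excess of seed matches over shuffled sequence. This test, fixed before any result of it was seen, was not run: at the listed positions G preceded 8.37% of the mitochondrial clusters in the reference used here, against 87.5% of nuclear clusters, so the reference sequence is not the one the positions refer to, and positions were not converted. Without it, AGO2 binding and abundance cannot be told apart for these clusters. No biological explanation was tested.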

How the results depend on the processing

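The seed tests with merged clusters, without hairpins and with 3' UTR flanks, the 5 human families left out, reordered 7mers, non-coding exons before introns and matching on 3' UTR length were chosen after seeing the data. Merging clusters whose spans from start to end overlapped left 23645 of 27633. The span of a spliced cluster includes its intron, so clusters that share no base could be merged. The 3' UTR share was 55.3% with strand ignored and 55.7% with any overlap of at least 1 nt, just above the interval of the main value, because a cluster touching 2 regions then goes to the 3' UTR. With strand ignored the intergenic share fell from 5.40% to 3.37% and the intron share rose from 10.2% to 12.2%, since genes of both strands then count. With non-coding exons first the intron share was 6.77%. Between 31 and 35 seed families were enriched under the 7 alternatives for the count, against 32. The ratio of clusters with a match to any enriched family ran from 1.92 with 6mers to 3.62 against the antisense strand; since these families were chosen for enrichment in the same clusters, a ratio above 1 is no separate evidence. Over these alternatives and the 5 human families left out, of 303 values of single families 280 kept their direction and side of the threshold, 8 lost their call, 9 gained one and 6 turned direction. Those were miR-24 at 0.768 with 6mers, miR-150 at 1.13, miR-122 at 0.912 and miR-K12-12 at 1.55 against shuffled copies, and miR-124 at 1.16 and miR-1/miR-206 at 0.890 against the antisense strand; the cause was not tested. Against 7mers of the same letters in another order, the ratio of 18 of the 41 families moved out of its interval, and 25 of the 32 enriched families exceeded at least 95% of their reordered 7mers. The other 7 were miR-K12-6-3p (just under that limit), miR-122 (93.3%), miR-34a (91.9%), miR-K12-1 (89.7%), miR-128 (83.0%), miR-K12-5 (74.7%) and miR-1/miR-206 (60.3%). Of the gene lists, 9 were called in the main test, 7 when matched on 3' UTR length and 0 against genes with any cluster, a background in which 87.8% of genes have an exon cluster and few can differ. The alternatives that keep the top 50% of scores were not run because all scores are equal. Those for the comparisons of DG75 with BCBL-1, leaving out each replicate included, were not run because the list names no line or library. No paired analysis was possible because the list carries no library. Without read counts, the strength of binding at a cluster was not measurable here.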

Other observations

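The tests of coding exons against 3' UTRs per family, of the bases beside AACACTA and of GGTTCGA were chosen after the data were seen, as was the final form of the test of hairpins that share a 20-mer; the tests of the share of coding-exon clusters with a match and of hairpin pairing were fixed before their results were seen. Genes with most matches per family, likewise chosen after their values were seen, included TNFRSF10B, a death receptor on the list of reported KSHV targets, with 4 clusters matching miR-K12-1. IL2RB, the beta chain of the interleukin-2 receptor, had 42 clusters, 5 of them matching miR-34a and 5 matching miR-K12-6-5p. The zinc finger gene ZNF107 had 10 clusters matching miR-K12-3 and 7 matching human miR-23, and ZNF850 had 6 matching miR-K12-10a and 6 matching miR-K12-3. FBN1, which encodes fibrillin, had 30 clusters, with 7 matching miR-181, 6 matching miR-K12-3 and 3 matching miR-23. The miR-K12-3 site shares 6 bases with the miR-181 site and 6 with the miR-23 site, so a cluster can count for several of these families.

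Families differed in how their enrichment was divided between coding exons and 3' UTRs, but the background decided most calls. MiR-142-3p was enriched 21.6-fold in coding exons and 7.56-fold in 3' UTRs over flanking windows, a ratio of 2.86 (95% interval 1.76 to 4.67). Against shuffled copies the ratio was 1.11 (0.907 to 1.35). After adjustment of a normal test of the log ratio over the 41 families, 8 differed over flanking windows and 12 over shuffled copies, and 2 differed under both, in the same direction. These were miR-101, lower in coding exons at 0.308 (0.177 to 0.536) and 0.442 (0.270 to 0.723), and miR-150, lower at 0.381 and 0.504. Over flanking windows miR-150 was enriched in neither region, at 0.248 in coding exons and 0.652 in 3' UTRs. Whether 2 families in common exceed what unrelated calls would share was not tested.

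Coding-exon clusters held a match to an enriched family less often (36.0%) than 3' UTR clusters (40.0%), with the families chosen for enrichment in clusters of all regions together. Reads from abundant mRNAs of the translation machinery were a candidate explanation. With genes of ribosomal proteins and translation factors left out, the share was 36.6% (35.4% to 37.7%), still below the lower bound of 39.2% in 3' UTRs. Those genes held only 241 of the 7288 coding-exon clusters, and 20.3% of these 241 had a match. They were too few to close the gap even if none had matched, so the outcome was fixed in advance. Other abundant mRNAs were not tested. Base composition was another candidate. Against dinucleotide-shuffled copies a difference remained, with a ratio of 2.70 (2.60 to 2.79) in coding exons and 3.10 (3.03 to 3.17) in 3' UTRs. Over flanking windows the ratios, 3.02 and 3.09, had overlapping intervals. The difference thus depended on the background, and base composition was not excluded. No biological explanation was tested.

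All 27394 nuclear clusters had different sequences. A candidate explanation is that only reads with 1 genomic match were kept, which would leave hairpins with near copies uncovered. Of 288 hairpins that share a 20-mer with another hairpin, 66 (22.9%) carried a cluster, against 315 of 1037 others (30.4%), an odds ratio of 0.682 (0.494 to 0.932, Fisher's exact test, p = 0.0150). That is consistent with the explanation, although lower expression of such hairpins was not tested. Hairpins were limited to 1 per locus and to named microRNA genes after a first definition had been seen to count duplicate records.

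Of 1325 annotated hairpins, 381 (28.8%) carried a cluster; those of miR-142, miR-155 and miR-17 were not analysed here. The hypothesis that the microRNAs of covered hairpins do not pair with the listed target clusters was tested on 318 hairpin clusters of at most 26 nt. Sites for bases 2 to 8 were not measurably more enriched in 3' UTR clusters than sites for bases 9 to 15, with a mean log2 difference of 0.086 (95% interval -0.015 to 0.185; sign-flip permutation test, p = 0.0946). The mean covers hairpins that go both ways, so it does not decide the question. Some hairpins, chosen after their values were seen, had far higher values for bases 2 to 8 than for bases 9 to 15, among them MIR301B (log2 2.58 and 0.07) and MIR181C (1.80 and -0.60), whose families are enriched in the clusters.

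AACACTA was the 7mer with the third highest ratio of the 15154 ranked, at 12.4 (1306 clusters), close to GCACTAC (376 clusters) and to the miR-142-3p site ACACTAC at 12.9; the median ratio was 0.977. It is the site of both miR-K12-10a and miR-142-3p shifted by 1 base, so it can pair with either without a further base. Pairing that extends to the next base of miR-142-3p would raise the share of matches preceded by A. That share was lower in clusters than in windows, at a ratio of 0.823 (0.680 to 0.994). The lower share concerns only the extended pairing and does not count against pairing of AACACTA itself with miR-142-3p. For miR-K12-10a the next base is C, with a ratio of 0.993 (0.725 to 1.36), which leaves extended pairing open. T preceded AACACTA more often, at 1.46 (1.15 to 1.86). Because the shares of the preceding bases add up to a whole, more T by itself lowers the other shares. The lower share of A therefore does not decide on extended pairing with miR-142-3p.

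The base before a cluster was G in 87.5% of nuclear clusters (87.1% to 87.9%) and 21.9% of flanking windows. The share was 94.1% in coding exons, 91.7% in 3' UTRs, 69.3% in introns, 52.6% in intergenic sequence and 46.1% on 568 clusters on any annotated hairpin, where the median width was 26 nt against 56 nt in 3' UTRs. Of the 1480 intergenic clusters, 24 (1.62%) contained GGTTCGA, a sequence typical of the T loop of transfer RNAs, against 4 of 15058 in 3' UTRs.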
